A study of Homo sapiens with 4 samples.

How the data were processed

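SMC1 HiChIP libraries of A673 cells, an Ewing sarcoma line that carries the EWS-FLI1 fusion, were compared between 2 STAG2-null and 2 wild-type libraries. HiChIP ligates DNA ends that lie close together in the nucleus and enriches by immunoprecipitation those bound by a protein, here SMC1, a core subunit of cohesin. STAG2 is one of the alternative STAG subunits of the same complex. Per the labels' protocols, formaldehyde-fixed chromatin was cut with a restriction enzyme, ligated, sonicated and precipitated with an SMC1 antibody, and the libraries were made by Tn5 transposition. The STAG2-null libraries came from Cas9-edited clones grown from single cells, per the labels' protocols. Nothing in the labels says that the libraries of a group are separate cultures, so p-values measure only the spread between these libraries, which may be technical.

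For each library the authors deposited a count of paired-end tags (PETs) for every pair of anchors that had at least 1, with a p-value per pair. HiC-Pro and the hg19 build are named, without versions, per the submitters' processing notes. The loop caller's settings, and whether the p-value per pair was adjusted, are not given in the sources used here. The median of that deposited p-value was 0.0151 for pairs with 1 PET and 0.408 for pairs with 2 PETs in the STAG2-null 1 library, so it was used only as an alternative filter. The 4 deposited count files shared one set of 79850 anchors, which did not change on merging within 500 bp and fell to 58469 on merging within 5 kb. A deposited table of 22680 high-confidence loops gives a count of PETs per library and a p-value per loop, per the file headers. The authors' deposited table of 650 differential loops gives a log2 fold change and a p-value adjusted by independent hypothesis weighting, per the file headers, with flags for CTCF, FLI1, H3K27ac and promoters at each anchor. Its largest adjusted p was 0.0998. The base of the log2 values was settled by setting them against the counts, and their sign by the column that names the genotype with the stronger loop. The names of the count columns of both tables give a genotype and not a library, so all counts given per library come from the per-library files. In differential loops compared, such as those at CAV1, ACTB and MCM7, the mutant and wild-type columns equalled STAG2-null 1 and 2 and wild-type 1 and 2 in order.

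The libraries held 682724 and 698002 PETs (STAG2-null 1 and 2) and 661881 and 765017 PETs (wild-type 1 and 2). Over the 4 libraries 1125468 anchor pairs had a PET, all within a chromosome and with midpoints at least 5 kb apart. A pair was tested as a loop where its PETs summed to at least 20, which kept 11872 loops, 1.05% of the pairs, with between 15.0% and 16.7% of the PETs of a library. Loop counts were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on genotype alone, after TMM scaling. Library totals were taken over all pairs and TMM factors over the tested loops, at 1.01, 1.05, 0.988 and 0.950 in the order above. Adjustment was by Benjamini-Hochberg, and calls were made at an adjusted p under 0.05. For promoters, the PETs of all pairs at the anchor holding a gene's transcription start were summed and tested the same way. Promoter positions came from the authors' deposited table of differential loops. It names 405 genes at an anchor, of which 251 could be placed directly, 23 by elimination and 131 not at all, leaving 274 genes at 218 anchors. Of the 405 names, 349 were current symbols and 39 older symbols in a RefSeq list of assembly GRCh38.p14, used only for names and for the number of genes per chromosome. Gene lists and length classes were tested with limma 3.58.1 (camera with a preset correlation of 0.01, camera with an estimated correlation, and fry). Shares of loops were compared with two-sided Fisher's exact tests in scipy 1.17.1, which treat loops as independent, and Mantel-Haenszel odds ratios came from statsmodels 0.14.6.

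Regional differences were measured on sparse anchor pairs, those with at most 4 PETs over the 4 libraries (1009021 pairs), as log2 ratios of library shares per chromosome and per 10 Mb window with at least 3000 such PETs. Where a group held 0 PETs, the fold was computed against a floor of 3 PETs over the group and given with the lower exact 95% binomial limit. With 1 to 3 PETs, the ratio of summed PETs is given with its exact 95% binomial interval. Shares of single libraries carry 95% Wilson intervals. Intervals and floors cover counting error only. Normalised PETs are PETs over the TMM-scaled library size, on a scale of 1000000, and errors of log2 fold changes are standard errors of the fit.

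The tests, the gene lists, the other settings to try and the rule for named loops and genes were set before the data were examined. The rule took the 10 loops with the smallest p per direction. It also took the 10 genes with the largest change per direction whose libraries separated by group, list members past the threshold, and STAG2, STAG1, NR0B1, NKX2-2, CCND1, PRKCB and LIPI where measured. Of the genes so named, 1 is not reported here. Those settings covered RLE factors, plain library totals, count minimums of 10 and 40, DESeq2 1.42.0, the replicate number as a block, leaving out each library, and scaling per chromosome and per length class. They also covered anchor merging, a 20 kb minimum length, the deposited p-value, discordant replicates, the high-confidence loops, other length limits and the overlap with the authors' table. Scaling per 10 Mb window, leaving out chromosomes 4, 7, 9, 16 and 19, an adjusted p limit of 0.1, the strata for loop classes, the pooled class of 20 to 200 kb and both regional scalings of the gene lists were chosen after seeing the data. The scripts were tested on simulated counts with known changes. For loops, 8% of 100 changed 2-fold and 52% of 100 changed 4-fold were recovered among 11872, with 6 unchanged loops called. For genes, 95% and 100% of 20 each were recovered among 274, with 3 unchanged genes called. A simulated length shift of 0.3 was returned as 0.33.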

Results

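SMC1-bound contacts were measured in 2 STAG2-null and 2 wild-type libraries of A673 cells. Each library held between 661881 and 765017 PETs over 417980 to 471677 anchor pairs, and between 73.3% and 74.7% of the pairs in a library rested on 1 PET. Across the 11872 tested loops, log2 counts of the STAG2-null libraries correlated at r = 0.531 and those of the wild-type libraries at r = 0.547, against 0.427 to 0.481 between genotypes. These correlations are across loops, which are not independent replicates. The spread between libraries over that of Poisson sampling was 1.18 for the STAG2-null pair, 1.07 for the wild-type pair and 1.22 to 1.5 between genotypes. STAG2 itself had no placed promoter anchor, and SMC1 contacts do not measure its transcript, so the knockout could not be checked here.

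The series design asked which loops of A673 cells differ with and without STAG2. A 684-kb loop lay at the promoter of MEIS1, a homeobox transcription factor. It held 5 and 15 PETs in STAG2-null cells and 0 and 0 in wild-type cells. The fold was 6.45 against the floor set for groups with 0 PETs, with a lower exact binomial limit of 4.78. This loop joined chromosome 2 positions 65973405 to 65977942 with 66650942 to 66668791 (hg19). A 56.5-kb loop to the promoter of CAV1, which encodes the main coat protein of caveolae, rose from 21.9 ± 5.73 to 53.3 ± 0.379 normalised PETs (SD, n = 2), a log2 change of 1.29 ± 0.33. The 105-kb loop of RXRA, the retinoid X receptor alpha gene, fell by 1.97 ± 0.43 on the log2 scale, from 36.1 ± 3.46 to 9.32 ± 9.34 normalised PETs (SD, n = 2), with a value of -3.64 without STAG2-null 1 and of -1.14 without STAG2-null 2, then not past the threshold. Of the 15 loops that were lower in STAG2-null cells, 11 lay on chromosome 9.

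Among the 11 loops higher in STAG2-null cells, a 13.1-kb loop at the promoters of DHPS and MAN2B1 held 22 PETs against 1 (ratio 21.3, 95% interval 3.44 to 879). A 154-kb loop from the promoter of KLF10, a zinc finger factor induced by TGF-beta, held 27 against 3 (8.71, 2.68 to 44.9). A loop at CRYAB, a small heat shock protein gene, and DIXDC1 held 21 against 2 (10.2, 2.48 to 89.4). Larger counts stood behind the loops at ACTB (log2 1.55 ± 0.37), at SLC3A2 and WDR74 (1.29 ± 0.30), at MCM7, a subunit of the replicative helicase, with AP4M1 and COPS6 (1.0 ± 0.23), and at KIRREL (0.96 ± 0.24, and 0.62 without STAG2-null 2, then not past the threshold). A 6.91-kb loop inside XXYLT1 rose by 1.99 ± 0.46. The loop at ADAT1 on chromosome 16, outside the rule for named loops and chosen after its value was seen, completed the set with 26 PETs against 4.

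Among the lower loops, the 102-kb loop from RNF208 and TUBB4B fell by 2.75 ± 0.59 and the 69.4-kb loop of C9orf62 fell by 2.26 ± 0.51. A loop over ABL1, which encodes a tyrosine kinase, fell by 2.47 ± 0.61 and one to NTMT1 and C9orf50 fell by 1.09 ± 0.25. On chromosome 9, loops starting at 132073682 and 132240582 without a named promoter fell by 1.02 ± 0.22 and 1.22 ± 0.29. Off chromosome 9, the loop over SMOX on chromosome 20 held 1 PET against 19 in wild-type cells (ratio 19.6, 3.12 to 816). The loop over RAI1, SREBF1 and TOM1L2 on chromosome 17 held 2 against 20 (10.3, 2.51 to 91.2), and a loop starting at 148155 on chromosome 7 held 2 against 21 (10.8, 2.65 to 95.4).

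The adjusted p of these 26 loops ran from 0.00952 (MEIS1) to 0.0456 (RXRA, a shorter loop of 31.6 kb) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 571 loops were higher and 579 lower at an unadjusted p under 0.05. Scaling each chromosome to its own total kept 9 of the 26 and gave 9 higher and 1 lower loop, the addition being a loop at the DAPK1 promoter on chromosome 9 (log2 1.16 ± 0.28). That loop stood at 0.76 ± 0.30 without this scaling (adjusted p = 0.339 in edgeR) and at 0.81 ± 0.28 with scaling per 10 Mb window (adjusted p = 0.431), and sparse pairs of its window, from 90 to 100 Mb, at 0.06. Scaling each 10 Mb window kept 3, those of MEIS1, SLC3A2 with WDR74, and KIRREL, with none lower (664 loops higher and 249 lower unadjusted). Of the 23 loops no longer called, 22 kept their direction at an unadjusted p under 0.05, and several kept their size, among them those of DHPS and MAN2B1 (4.11 to 3.88, adjusted p = 0.0532 in edgeR), CRYAB (3.19 to 3.27, 0.0541), ACTB (1.55 to 1.52, 0.0774) and the chromosome 7 loop starting at 148155 (-3.28 to -3.32, 0.0532). Others shrank, such as the 31.6-kb loop of RXRA (-0.95 to -0.39), the loop to NTMT1 (-1.09 to -0.52) and the chromosome 9 loops starting at 132073682 (-1.02 to -0.45) and 132240582 (-1.22 to -0.64). With anchors merged within 5 kb, which pools neighbouring pairs, 1 of the 13 named loops matched still passed, that of SLC3A2 with WDR74 (1.28). The MEIS1 loop then had an adjusted p of 0.0795 in edgeR, and those of ABL1, NTMT1, RNF208 with TUBB4B, C9orf62 and KIRREL stood at -0.50, -0.59, -0.83, -0.89 and 0.41, the chromosome 7 loop at -1.73 and the SMOX loop at -0.77. Scaling per chromosome and per window took the totals of each region in place of TMM factors. The median of all tested loops moved from -0.04 to 0.11 and 0.12 with them. That common shift favours higher over lower loops and enters the sizes given after scaling, beside any regional difference removed. Plain library totals gave 11 higher and 5 lower loops, and scaling per length class gave 8 and 2. DESeq2 called 0 and 0 (57 and 84 unadjusted). Without wild-type 1 edgeR called 0 and 0 (472 and 480 unadjusted), without wild-type 2 again 0 and 0 (411 and 448), without STAG2-null 2 it called 0 higher and 1 lower (339 and 370), and without STAG2-null 1 it called 3 and 4.

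**Figure D1:**
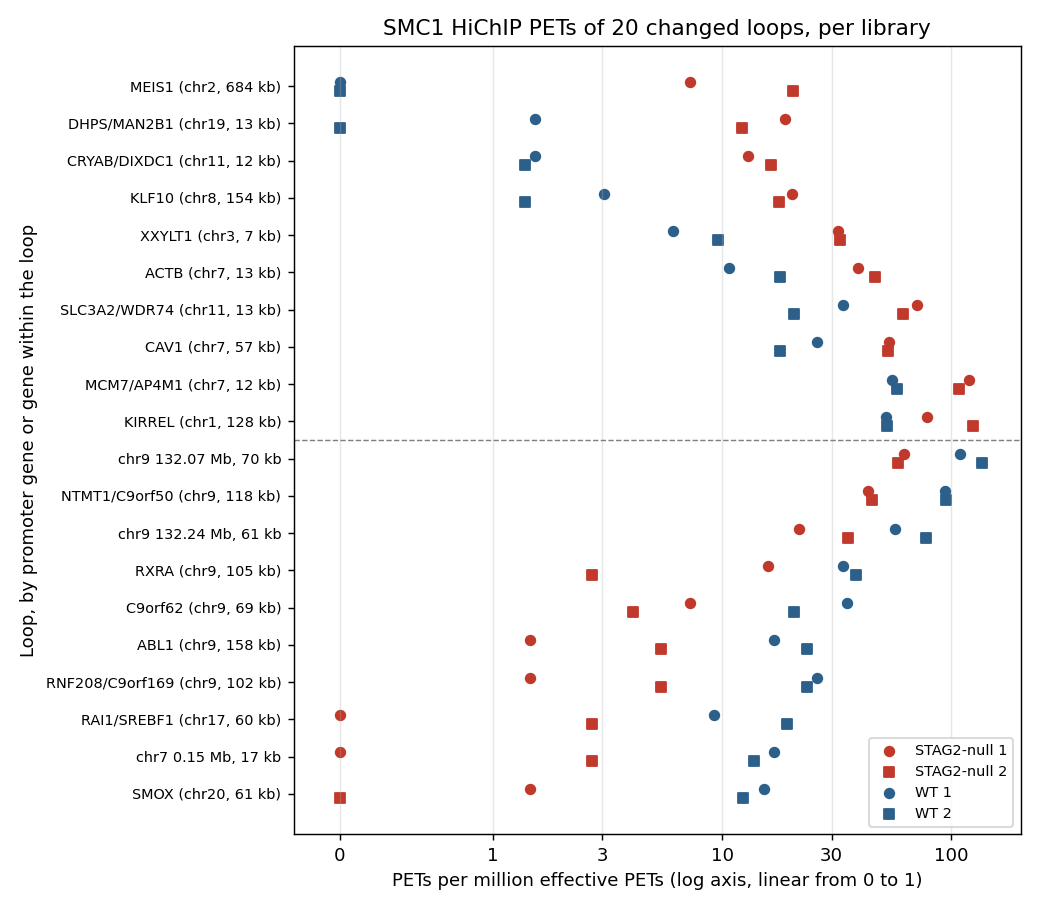
PETs per 1000000 effective PETs (x axis, logarithmic above 1 and linear from 0 to 1) of the 20 named loops, with 1 point per library, STAG2-null in red and wild type in blue. Loops above the dashed line were higher in STAG2-null cells, with the MEIS1 loop at 0 in both wild-type libraries, and 7 of the 10 below it lay on chromosome 9.

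Summed over each promoter anchor, contacts of 46 of 274 genes were higher and those of 78 lower in STAG2-null cells, at 39 and 59 anchors. The promoter of KLF10 on chromosome 8 gained most, from 11.5 ± 3.25 to 37.8 ± 2.29 normalised PETs (SD, n = 2; log2 1.69 ± 0.42). The promoter of HGFAC, which encodes the protease that activates hepatocyte growth factor, fell by 1.25 ± 0.18, from 167 ± 13.2 to 70.4 ± 13 normalised PETs (SD, n = 2). MSX1, a homeobox gene of the neural crest, fell by 1.01 ± 0.28, with values of -1.66 without STAG2-null 1, -0.51 without STAG2-null 2 and -0.70 for loops of at least 20 kb, the latter 2 not past the threshold. Chromosome 9 held 42 of the 78 lower genes, at 30 anchors, and 0 higher ones among 45 genes tested. Chromosomes 19 and 7 held 15 and 10 of the 46 higher genes, at 10 anchors each, and 0 lower ones among 32 and 27 tested. Genes at a shared anchor have the same counts.

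Other genes with large gains were ADAT1, a tRNA deaminase gene (0.98 ± 0.26), CARM1, an arginine methyltransferase gene (0.93 ± 0.22), USE1 (0.89 ± 0.28) and MOSPD3 (0.83 ± 0.21). RERE (0.80 ± 0.28), B3GNT9 (0.75 ± 0.22), ACTR3B (0.74 ± 0.22) and SEPN1 (0.72 ± 0.26) followed. On chromosome 9, QRFP (-0.96 ± 0.14), VAV2, a guanine nucleotide exchange factor gene (-0.83 ± 0.14), RXRA (-0.77 ± 0.17), TOR2A (-0.77 ± 0.13) and FIBCD1 (-0.76 ± 0.13) were lower. Elsewhere, DACT2 on chromosome 6, a modulator of Wnt signalling (-0.93 ± 0.28), PKNOX2 on chromosome 11, a homeobox gene (-0.81 ± 0.25), and RUFY4 on chromosome 2 (-0.79 ± 0.15) were lower. Adjusted p of these genes ran from 3.67e-07 (HGFAC) to 0.0200 (SEPN1) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

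The 274 genes are those the authors' deposited table of differential loops names at a placed anchor, so they were picked for change and their share of calls is no genome-wide rate. Scaling per chromosome called 15 higher and 10 lower, 22 of them among the 124 above, including KLF10 (1.78), MEIS1 (0.81), CRYAB (0.87), the Wilms tumour gene WT1 (-0.52), HGFAC (-0.80) and QRFP (-0.57). Of the named genes, VAV2, RUFY4 and DACT2 passed as well, and CARM1, USE1, MOSPD3, RXRA, MSX1 and the others did not. A lost call need not mean a smaller change. KLF10 went from 1.69 to 1.78 while its adjusted p in edgeR went from 0.00106 to 0.0306. Scaling per 10 Mb window called 0 in edgeR (60 unadjusted, lowest adjusted p 0.0565, shared by KLF10, MEIS1 and WT1 among others). HGFAC then stood at -0.51, with sparse pairs of its window on chromosome 4 at -0.65. Plain library totals gave 61 higher and 62 lower genes, scaling per length class 64 and 63, and DESeq2 6 and 42. Without wild-type 1 edgeR called 0 genes (78 unadjusted), without wild-type 2 again 0 (73 unadjusted), without STAG2-null 1 it called 37 higher and 83 lower, and without STAG2-null 2 it called 34 and 60. Without STAG2-null 2, RXRA and TOR2A stood at -0.43 and -0.48, still past the threshold, and ACTR3B, DACT2, PKNOX2, RERE and SEPN1 no longer passed, nor did USE1, SEPN1 and DLX5 without STAG2-null 1. Without wild-type 2, ADAT1 and ACTR3B stood at 0.60 and 0.46. With anchors merged within 5 kb USE1 stood at 0.28, no longer past the threshold, and MOSPD3, B3GNT9, ACTR3B and RERE at 0.36, 0.41, 0.43 and 0.53, still past it. With loops of at least 20 kb USE1 (0.65) and RERE (0.66) no longer passed. In DESeq2 only 17 of the 23 genes that the rule named had a value, of which 10 stayed as before. RXRA, ADAT1, B3GNT9, ACTR3B, PKNOX2, SEPN1 and DLX5 did not pass, and genes without a value cannot be counted as passing.

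**Figure D2:**
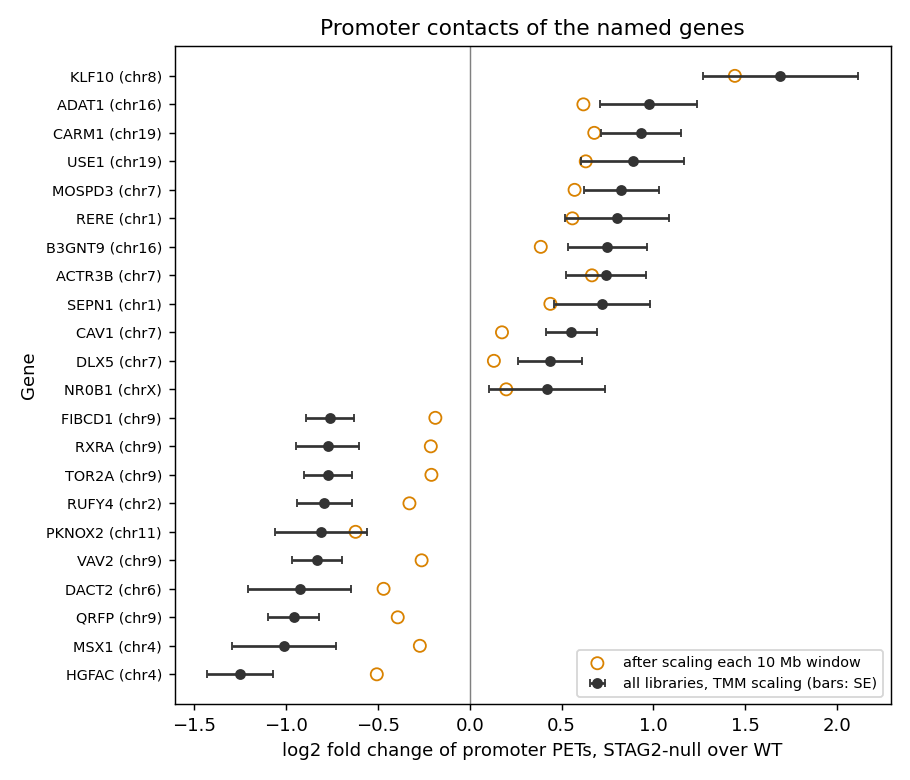
Log2 fold change of promoter PETs, STAG2-null over wild type (x axis), for 22 named genes, with filled points and SE bars from the fit to 4 libraries and open circles after scaling each 10 Mb window. KLF10 kept most of its gain after window scaling (1.69 to 1.44) but was no longer called (adjusted p = 0.0565 in edgeR), while chromosome 9 genes such as RXRA moved from -0.77 to -0.21.

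Of the EWS-FLI1-activated list, 4 genes had a placed promoter. CAV1 rose by 0.55 ± 0.14 and UGT3A2 (0.54 ± 0.23), NR0B1, an orphan nuclear receptor gene and EWS-FLI1 target (0.42 ± 0.32, with 0.75 without STAG2-null 1 and 0.03 without STAG2-null 2), and ETV6 (0.20 ± 0.14) did not pass the threshold, with 1 gene higher over all genes and 2 when adjusted over the list alone, in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The list median was 0.48, with a camera p of 0.0591 (adjusted p = 0.177 over 3 lists tested with limma's camera, and p = 0.367 with an estimated correlation). Without the STAG2-null 1 library the median was 0.65 and without the wild-type 1 library 0.46, each past a threshold of 0.05 in limma's camera before adjustment with the preset correlation (p = 0.269 and p = 0.487 with an estimated correlation). NR2F2, the sole EWS-FLI1-repressed gene measured, stood at 0.27 ± 0.15. Scaling per chromosome moved CAV1 to 0.39, no longer past the threshold, and scaling per window moved the list median to 0.21. STAG1, NKX2-2, CCND1, PRKCB and LIPI had no placed promoter.

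Of the neural crest and neurodevelopment list 2 genes were measured. DLX5 rose by 0.44 ± 0.17 and MSX1 fell, each also when adjusted over the list alone, and neither passed after scaling per chromosome (0.27 and -0.57). HOX genes were measured at 2 anchors, the HOXD anchor, which counts for 5 genes, at -0.18 ± 0.16 and the HOXB13 anchor at 0.07 ± 0.13, with 0 of 6 genes past the threshold also when adjusted over the list alone. Their median of -0.18 (limma's camera, adjusted p = 0.589, and adjusted p = 0.837 with an estimated correlation) turned to 0.04 with scaling per chromosome and 0.07 with scaling per window, and stood at -0.31 without STAG2-null 2, then past a threshold of 0.05 in camera before adjustment with the preset correlation (p = 0.302 with an estimated correlation). The 3 housekeeping genes measured, among them ACTB (0.17) and TUBB (0.16), had a median of 0.16 (limma's camera, adjusted p = 0.533), with 0 past the threshold over all genes or adjusted over the list alone. CDC20, the sole cell cycle gene measured, stood at -0.23 ± 0.13, and the cohesin, interferon and mesenchyme lists had 0 genes measured.

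Of 6 length classes, loops of 5 to 20 kb rose relative to all loops in STAG2-null cells, by 0.13 on the log2 scale (camera adjusted p = 0.000989, and adjusted p = 0.0209 with an estimated correlation), with 21.5 ± 0.935% of PETs against 19.6 ± 0.502% in wild-type cells (SD, n = 2). Loops of 20 to 50 kb stood at -0.08 relative to all loops (camera adjusted p = 0.0240, and adjusted p = 0.0767 with an estimated correlation), those of 50 to 100 kb at -0.21 (0.000911 and 0.0584) and those of 100 to 200 kb at -0.14 (0.00633 and 0.0868). Loops of 50 to 100 kb held 11.9 ± 0.119% of PETs against 13.1 ± 0.0930% in wild-type cells (SD, n = 2). The 88 loops over 500 kb stood at 0.36 (camera adjusted p = 0.00291, and adjusted p = 0.306 with an estimated correlation), with 18.2 ± 0.505% of PETs against 17.2 ± 0.364% (SD, n = 2), and loops of 200 to 500 kb passed neither way. The value of loops over 500 kb was 0.04 with at least 40 PETs per loop, 0.08 with anchors merged within 5 kb, 0.22 on the high-confidence loops and 0.15 without STAG2-null 2. That of loops of 5 to 20 kb was 0.03 without STAG2-null 2 and 0.08 with scaling per 10 Mb window.

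The planned length shift, the median of loops of at least 200 kb minus that of loops under 100 kb, was 0.08 (camera p = 0.304, and p = 0.418 with an estimated correlation) and turned to -0.10 without STAG2-null 2. Loops of at least 200 kb held 38.1 ± 0.665% of PETs in STAG2-null and 37.1 ± 0.602% in wild-type cells (SD, n = 2), a difference for which an exact permutation test cannot give a two-sided p below 0.333. Pooled after the values of the classes were seen, the 4411 tested loops of 20 to 200 kb had a median log2 change of -0.17, against -0.04 for all loops. Their value relative to all loops, -0.12, was -0.04 with anchors merged within 5 kb, -0.08 and -0.19 with at least 10 and at least 40 PETs per loop, and -0.02 where the comparison left out loops under 20 kb.

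**Figure D3:**
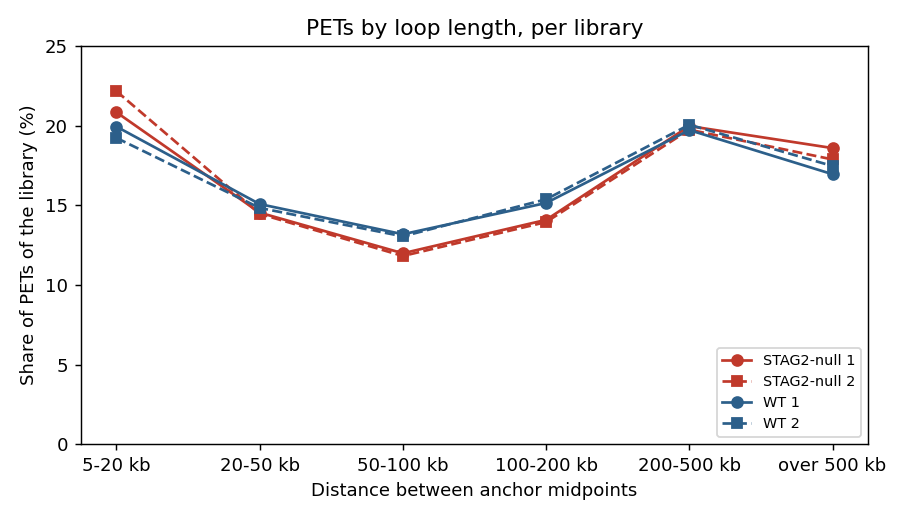
Share of PETs (%) by distance between anchor midpoints in 6 classes, with 1 line per library, STAG2-null in red and wild type in blue. At 50 to 100 kb both STAG2-null libraries (12% and 11.8%) lay below both wild-type libraries (13.2% and 13%).

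Whole chromosomes and parts of chromosomes differed between the genotypes in their total of contacts. Chromosome 9 held 7.53 ± 0.424% of PETs in STAG2-null and 9.29 ± 0.0101% in wild-type cells (SD, n = 2), a log2 ratio of -0.30, and chromosome 4 stood at -0.36. Chromosome 7 held 10.8 ± 0.0580% against 8.97 ± 0.0338% (SD, n = 2; log2 ratio 0.26), and chromosomes 16 and 19 stood at 0.33 and 0.25. The groups lay apart at 17 of 23 chromosomes, where chance gives a share of 33.3%.

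In windows of 10 Mb, sparse pairs on chromosome 9 stood at -0.36 and -0.49 between 120 and 140 Mb, the region of RXRA, VAV2 and ABL1, and between -0.00125 and 0.09 before 100 Mb. On chromosome 3, ratios of 0.44 to 0.58 beyond 150 Mb, the region of HES1 and BCL6, stood beside -0.10 to 0.13 before 140 Mb. The start of chromosome 1 up to 40 Mb stood at 0.28 to 0.39, the end of chromosome 2 beyond 170 Mb at -0.69 to -0.22, and chromosome 20 up to 30 Mb at -0.51 to -0.40. These stretches were picked after their values were seen. The ratio had an SD of 0.226 over 162 windows, against 0.115 between the STAG2-null libraries and 0.0542 between the wild-type libraries, and the groups lay apart in 74.1% of windows, where chance gives 33.3%. Over 117 windows with at least 20 tested loops, the median change of those loops followed the ratio of sparse pairs (Pearson r = 0.875 across windows, which are not independent replicates).

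**Figure D4:**
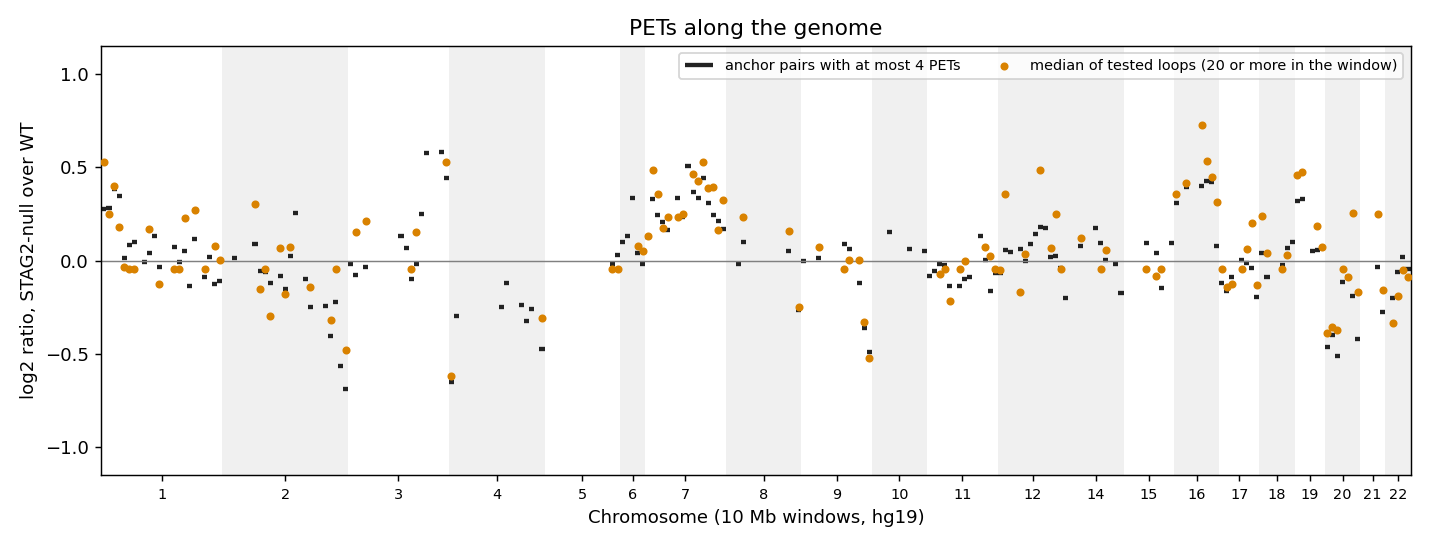
Log2 ratio of PETs, STAG2-null over wild type, along the chromosomes in 10 Mb windows, with black bars for anchor pairs of at most 4 PETs and orange points for the median of tested loops. The chromosome 9 end lies at -0.49 and chromosome 7 windows lie between 0.13 and 0.51, and windows under 3000 PETs, among them all of chromosomes 13 and X, are not drawn.

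The authors' deposited table lists 650 differential loops, 350 stronger in mutant and 300 stronger in wild-type cells. In the authors' deposited table, loops stronger in mutant cells had a median width of 12 kb and those stronger in wild-type cells one of 40.9 kb. Loops with H3K27ac, a mark of active enhancers and promoters, at both anchors made up 43.7% of the mutant-stronger and 27% of the wild-type-stronger loops of the authors' deposited table (odds ratio 2.10, Fisher's exact test with Benjamini-Hochberg adjusted p = 7.58e-05). FLI1, the DNA-binding part of EWS-FLI1, flagged both anchors of 8% against 2.33% in the authors' deposited table (odds ratio 3.64, Fisher's exact adjusted p = 0.00286). CTCF, the boundary factor at which cohesin stops, flagged at least 1 anchor of 66.6% against 81.0% in the authors' deposited table (odds ratio 0.467, Fisher's exact adjusted p = 0.000162).

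FLI1 at 1 or more anchors (30.6% against 20.7%, Fisher's exact adjusted p = 0.00665) and H3K27ac at 1 or more anchors (86.6% against 76.7%, 0.00286) differed likewise in the authors' deposited table, and CTCF at both anchors was less frequent among mutant-stronger loops (24.3% against 33.3%, 0.0154). Promoters at 1 or more anchors did not differ there (47.4% against 50.3% in the authors' deposited table, Fisher's exact adjusted p = 0.548), nor did promoters at both. Chromosome 9 held 36.0% of the wild-type-stronger loops and 11.1% of the 22680 high-confidence loops, and chromosome 7 held 20.9% of the mutant-stronger and 9.73% of the high-confidence loops in the authors' deposited tables (Fisher's exact p = 3.67e-29 and 6.60e-10, chosen after seeing the data). All 26 loops called here were in the authors' deposited table with the same direction. Of its 503 loops tested here, all had an unadjusted p under 0.05 and the same direction in edgeR, as did 455 after scaling per chromosome and 385 after scaling per window. The authors' deposited table rests on the same libraries, with equal counts where compared, as for the 56.5-kb CAV1 loop (37, 39, 17 and 13 PETs). Both matches were thus built in and are no independent support. The odds ratio for CTCF at both anchors of the authors' deposited table was 0.846 (95% interval 0.566 to 1.27) within length classes and 0.419 (0.262 to 0.670) within chromosomes, and that for CTCF at 1 or more anchors 0.624 (0.415 to 0.938) and 0.390 (0.243 to 0.628). Within chromosomes those for FLI1 at both anchors and at 1 or more in the authors' deposited table were 2.71 (0.996 to 7.36) and 1.81 (1.12 to 2.92), and that for H3K27ac at 1 or more was 1.69 (0.994 to 2.87).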

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

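Of the tests in this part, those on gene density and on the size of loops after scaling and the limit of 0.2 on the log2 scale for naming a chromosome were chosen only after the result was seen. Sparse anchor pairs, which enter no loop test and are taken here as mostly background, held more PETs in STAG2-null than in wild-type cells on chromosome 7 (log2 ratio 0.25, pooled SD 0.00409), chromosome 16 (0.31, SD 0.0205) and chromosome 19 (0.22, SD 0.0268). They drew attention because pairs outside the loop comparison rose above the wild-type level in both STAG2-null libraries. By the same limit, sparse pairs held fewer PETs in STAG2-null cells on chromosomes 4 (-0.34, SD 0.0293), 9 (-0.27, SD 0.0551) and 20 (-0.23, SD 0.0479).

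A difference in copy number between the STAG2-null and wild-type cells is a candidate explanation for these shifts, which needs tested loops to move with the background, and the slope of their median change on the ratio of sparse pairs over 23 chromosomes was 1.10 (jackknife 95% interval 0.794 to 1.40). Of the 15 loops called on chromosomes 7 and 9, 2 remained past the threshold after scaling per chromosome, a count that decides nothing, since these calls lay near the threshold and a moderate shift ended them. Their median log2 size went from 1.75 to 1.39 (median standard errors 0.43 and 0.45) and to 1.41 with scaling per 10 Mb window, with 15 and 14 still at an unadjusted p under 0.05 in edgeR. These loops were picked for large change. Removing regional shifts of the size seen here could not have taken most of it away, so these values do not decide between copy number, chance and other causes. Against a library bias toward gene-dense chromosomes as the whole cause, the 6 most gene-dense autosomes moved apart, 19 and 16 at 0.22 and 0.31 and 17, 11, 22 and 20 at -0.11, -0.08, -0.06 and -0.23, with a Spearman correlation of 0.129 between ratio and gene density over 22 autosomes (permutation p = 0.564; Pearson r = 0.239, permutation p = 0.290, and 0.104 without the 2 farthest chromosomes). Whether a copy number difference would come from the cloning of single cells or from the loss of STAG2 stays open, as the STAG2-null libraries are clones and the origin of the wild-type cells is not stated in the labels.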

How the results depend on the processing

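Scaling per 10 Mb window, leaving out chromosomes 4, 7, 9, 16 and 19, the adjusted p limit of 0.1, the strata for loop classes and both regional scalings of gene lists were chosen only after the result was seen. Of the results that answer a comparison, 97 values kept direction and side of the threshold across alternatives, 42 became weaker, 7 stronger, 3 moved and 5 reversed. Over named loops and genes 492 values stayed, 274 became weaker, that is lost their call, and 1 reversed, NR0B1 at -0.16 with loops of at least 20 kb. The cause of the changes below was not tested except where fewer loops or libraries entered. Regional scaling removes regional differences, but the gene calls lost with it do not rest on that alone. With scaling per window the MEIS1 promoter went from 0.60 ± 0.14 to 0.61 ± 0.12, while its unadjusted p in edgeR went from 4.88e-05 to 0.000272. The KLF10 promoter went from 1.69 ± 0.42 to 1.44 ± 0.36, with a p of 0.000152 and then 0.00178 in edgeR.

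From 11 higher and 15 lower loops, a minimum of 10 PETs gave 6 and 4, a minimum of 40 gave 7 higher, DESeq2 0 and 0 (57 and 84 unadjusted), and merging anchors within 5 kb 2 and 3. Loops of at least 20 kb gave 4 and 5, plain totals 5 lower, scaling per chromosome 1 lower, per length class 2 lower, and per window 3 and 0 (664 and 249 unadjusted). The high-confidence loops gave 6 lower (5 with the deposited counts), leaving out chromosomes 4, 7, 9, 16 and 19 gave 4 and 1, and an adjusted p limit of 0.1 gave 26 lower. From 46 higher and 78 lower genes, DESeq2 gave 6 and 42, scaling per chromosome 15 and 10, per window 0 and 0 (60 unadjusted), loops of at least 20 kb 48 lower, leaving out those chromosomes 26 and 36, and the limit of 0.1 gave 70 higher. Leaving out 1 library, with the lone library of a group assumed to vary like the other group, gave 0 to 3 higher and 0 to 4 lower loops and 0 to 37 higher and 0 to 83 lower genes. The 274 genes were picked for change on these same libraries, so small unadjusted p-values in these fits are no independent support.

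The length shift of 0.08 rose to 0.23 with loops of at least 20 kb and 0.28 for loops of at least 500 kb against those under 50 kb, both then past 0.05 in limma's camera with the preset correlation (p = 0.110 and p = 0.255 with an estimated correlation), and ran from -0.10 to 0.17 with 1 library left out. The difference of 0.995 percentage points in long loops became -0.250 at a limit of 100 kb, 2.39 with loops of at least 20 kb and 1.94 with deposited p-values under 0.01, and ran from 0.525 to 1.47 with 1 library left out. The median of the EWS-FLI1-activated list ran from 0.30 to 0.65 with 1 library left out, 0.46 without wild-type 1, and that of HOX genes from -0.31 to -0.017, turning to 0.036 with scaling per chromosome and 0.068 per window. Odds ratios of loop classes moved to 0.846 (CTCF at both anchors, within length classes), 2.71 (FLI1 at both) and 1.69 (H3K27ac at 1 or more, both within chromosomes), and those of promoters reversed to 1.24 and 1.23 within length classes.

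Libraries with the same replicate number share only a number, and their differences did not go together (r = 0.00265 over loops). With the replicate number as a block, 9 loops were higher and 15 lower, and 35 genes were higher and 71 lower, and of those named the CRYAB loop, RERE, SEPN1 and DLX5 no longer passed. At this depth 8% of simulated 2-fold changes were recovered among 11872 loops and 95% among 274 genes, which differ in counts and in the number of tests.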

Other observations

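The comparison of loops by gene list, the use of the status marks and the genes named in the opening of this part were chosen only after the result was seen, as were the strata for flagged loops, scaling per 10 Mb window, the pooling of loops of 20 to 200 kb and the test of a shared profile in loops of 5 to 20 kb. The authors' deposited table holds 10 loops that name a gene of the EWS-FLI1-activated list, 9 stronger in mutant cells and 1 in wild-type cells, against 341 of the other 640. The mutant-stronger loops in the authors' deposited table lay at GSTM4, UGT3A2, JARID2, STEAP2, CAV1, ETV6, PRKCB, a kinase gene, and NR0B1, and the wild-type-stronger one at KCNAB3. Their odds ratio in the authors' deposited table was 7.89 (Fisher's exact p = 0.0242, adjusted p = 0.169 over 7 lists), so the difference did not pass the correction, and the table was itself picked for change. Of the 9 mutant-stronger loops in the authors' deposited table, 4 (STEAP2, PRKCB and both CAV1 loops) lay on chromosomes 7 and 16, whose sparse pairs summed to a log2 ratio of 0.25 and 0.31. In the counts per library 7 of the 10 were tested, and 6 kept their direction at an unadjusted p under 0.05 in edgeR after scaling per 10 Mb window. That scaling moved the NR0B1 loop of 6.15 kb from 1.36 ± 0.47 to 1.13 ± 0.48 on the log2 scale, the GSTM4 loop of 58.5 kb from 1.75 ± 0.68 to 1.92 ± 0.67, and the CAV1 loops of 56.5 and 24.7 kb from 1.29 ± 0.33 to 0.91 ± 0.32 and from 0.86 ± 0.36 to 0.48 ± 0.37, none then past the threshold over all loops. All 5 loops naming HOX genes were stronger in mutant cells in the authors' deposited table (Fisher's exact p = 0.0652, adjusted p = 0.228). They lay at HOXD on chromosome 2 and at HOXB on chromosome 17, where the loops of 211 and 203 kb shared an anchor, so they are not independent. In the counts per library the 513-kb HOXD loop stood at 0.66 ± 0.27 and the 203-kb loop, which spans HOXB13, at 1.97 ± 0.66. Neither passed the threshold over all loops (adjusted p = 0.384 and 0.221 in edgeR).

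Genes marked DN in a status column whose meaning is not given in the sources used here included IGFBP2, ROR2 and ZBTB16 at wild-type-stronger and CAV1, DLX5 and HES1 at mutant-stronger loops of the authors' deposited table. Over the authors' deposited table, 13 DN and 2 UP genes stood at wild-type-stronger loops and 7 DN and 6 UP genes, among them NR0B1, BCL6 and ROR1, at mutant-stronger loops (Fisher's exact p = 0.0957). Most marked genes were UNCH, with 23 at wild-type-stronger and 48 at mutant-stronger loops, and 4 marked genes stood at loops of both directions. The mitochondrial genome held 617 and 2013 PETs in the STAG2-null libraries and 987 and 1037 in the wild-type libraries.

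The lower median of loops of 20 to 200 kb relative to all loops was weighed against a copy number difference, a single library and a profile shared by all contacts. Scaling per chromosome left the 20 to 200 kb loops at -0.142 ± 0.0164 relative to all loops (jackknife SE over chromosomes) and scaling per window at -0.143, and leaving out any 1 of the 4 libraries left them at -0.135 or lower, which argues against copy number and a single library. Sparse pairs of 20 to 200 kb stood at -0.10 relative to all sparse pairs (pooled SD 0.00568), 0.793 times the value of tested loops. That ratio cannot decide, as both values rest on different mixes of lengths. Loops of 5 to 20 kb made up 6776 of the 11872 tested, and without loops under 20 kb the tested value was -0.02. Within their own set, sparse pairs were lower at 20 to 50, 50 to 100 and 100 to 200 kb (-0.05, -0.12 and -0.11). A profile shared by all contacts of a library, as a difference in ligation or fragmentation could give, thus remains possible at these lengths. In loops of 5 to 20 kb it stays open, with sparse pairs at 0.0182 (pooled SD 0.0295) beside tested loops at 0.13, or 0.08 after scaling per window and 0.03 without STAG2-null 2. An effect of STAG2 loss on the distance of all contacts would show the same profile and stays open with it.

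The higher share of H3K27ac and FLI1 flags among mutant-stronger loops of the authors' deposited table may rest on properties other than the flags. Within length classes the odds ratio for H3K27ac at both anchors in the authors' deposited table was 3.05 (95% interval 2.03 to 4.58), and that for FLI1 at both 4.65 (1.68 to 12.9), which argues against the shorter length of these loops as the cause. Within chromosomes they were 2.63 (1.67 to 4.15) and 2.71 (0.996 to 7.36) in the authors' deposited table, and that for FLI1 at 1 or more anchors was 1.81 (1.12 to 2.92), which argues against whole-chromosome copy number for H3K27ac at both anchors and FLI1 at 1 or more and leaves it open for FLI1 at both, where the interval includes 1 (regions within chromosomes were not set apart). A rise of all contacts at FLI1-flagged anchors stays open, as the 763 tested loops at such anchors outside the table had a median of -0.00712 relative to all loops after scaling per window (SE over chromosomes 0.0140) and of -0.00390 without it (SE 0.0924), a set that leaves out loops that changed, and with them the values were 0.0138 (SE 0.0376) and -0.00199 (SE 0.0909), against 0.000619 (SE 0.0209) and -0.00289 (SE 0.0874) at H3K27ac-flagged anchors. Flags were known only for anchors of the authors' deposited table. Tested loops outside it at any of these anchors stood at -0.0309 (SE 0.0132) after scaling per window and -0.0657 (SE 0.0589) without it. A loop-specific effect of STAG2 loss remains a hypothesis, since genotype and clone coincide.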
